A study of Mus musculus with 18 samples.

How the data were processed

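The series held 18 mouse samples. Bulk RNA sequencing covered 9 skin libraries, with 3 each labelled mock, PDMS (polydimethylsiloxane, a silicone) and X90, and 6 macrophage libraries, with 3 each labelled P90 and PDMS. Single cell RNA sequencing covered 3 libraries, 1 each labelled Mock, PDMS and H90. Skin RNA was extracted with a column kit and made into libraries with a SMARTer mRNA kit, per the labels. The labels name mm10 as the genome build for every group. The aligner, the counting program and the gene annotation are not given in the sources used here.

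The bulk tables hold 51 value columns, named by unit per the file headers. Each library has expected counts per gene, which the authors estimated from the reads and which are not always whole: 5.72% of the skin values and 4.81% of the macrophage values had a fraction. Each library also has FPKM and TPM, which the authors scaled for gene length and library size. The 15 TPM columns sum to the same total in every library and were not tested. The macrophage table adds 6 columns of normalized signal, which are the authors' read counts divided by 1 factor per library, and these served only as a scaling alternative. The single cell cell table holds deposited counts of UMIs (unique molecular identifiers) and genes per cell, the deposited percent of mitochondrial UMIs, and cluster numbers and type names by the authors. The single cell gene table holds signal values per cluster and library, which the authors made as means over cells of UMIs scaled to 10000 per cell. It also holds log2 fold changes and shares of cells that the authors computed between libraries within clusters, and these were not used here. No table of UMIs per gene and cell was used here.

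Expected counts were rounded and fitted in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr with default settings, robust quasi-likelihood F test). The 9 skin libraries formed 1 fit and the 6 macrophage libraries another. The filter kept 15156 of 18728 genes in skin and 11031 of 14755 in macrophages. P-values were adjusted by Benjamini-Hochberg over all tested genes, and a gene was called at an adjusted p under 0.05 with no fold threshold. Errors of log2 fold changes are standard errors (SE), and errors of FPKM are standard deviations (SD) over 3 libraries. Total expected counts ran from 16301000 to 17770100 per skin library and from 17963600 to 18740100 per macrophage library. The biological coefficient of variation was 0.373 in skin and 0.142 in macrophages. TMM factors ran from 0.956 to 1.07 in skin and from 0.852 to 1.18 in macrophages.

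Before the data were examined, 30 gene lists for processes and cell types, the comparisons, the tests, the alternatives and the rule for naming genes were fixed. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM, with a preset correlation between genes of 0.01, and adjusted over the lists of a comparison. Camera with a correlation estimated per list and fry, which tests a list by itself, were run beside it. Changes within a list were also adjusted over the list alone. For each list, a library was counted as showing the direction when its mean over the list lay beyond those of all 3 libraries of the other group. The rule for named genes took S100a8 and S100a9 in every comparison, and the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose higher group had a mean of at least 1 FPKM. Predicted genes, immunoglobulin genes and T cell receptor genes were left out of these, and up to 4 members with the smallest p per list were added. In the single cell data the rule took the 5 largest differences in each direction between H90 and PDMS, per cell class with at least 50 cells in both libraries, with a mean of at least 0.5 per 10000 UMIs and a 2-fold difference. Genes named outside these rules were chosen after their values were seen.

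Pooled single cell clusters were named from fixed marker genes, where at least 3 markers of a class led by a set margin. This naming rule was refined after the data were seen, because the authors' type names went against the leading genes of several clusters. Shares of cells were computed from the cell table with exact 95% Clopper-Pearson binomial intervals in Python 3.11.15 with scipy 1.17.1, and tables were handled with pandas 2.3.3. These intervals cover counting error only. Removal of doublets (2 cells read as 1) is not given in the sources used here, and none was made here. Pooled cluster 17, unnamed, was led by mast cell genes (Cma1 and Tpsb2) with T cell genes (Trdc and Cd3g). With 1 library per group, no test of shares or levels between the single cell libraries was made. The only p-value that uses single cell data is a sign test over Hox genes, which counts genes and not libraries.

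The tests were run on simulated counts with 200 changed genes, drawn from the means, dispersions and library sizes of each comparison. Genes were drawn independently, and so many changed genes make the adjusted threshold easier to reach than in the real skin fits. For X90 against PDMS in skin, edgeR recovered 23.9% of genes changed 2-fold, 71.6% at 4-fold and 89.4% at 8-fold, with 9 false calls among 132. For PDMS against mock it recovered 13.4%, 68.7% and 75.8%, with 6 false calls among 111. For X90 against mock it recovered 8.96%, 56.7% and 81.8%, with 8 false calls among 106. In the macrophage comparison it recovered 86.6%, 98.5% and 100%, with 21 false calls among 211. DESeq2 made false calls at shares of 25.4%, 28.9%, 27.2% and 14.5% in the same order.

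The alternatives were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, limma-trend on log2 FPKM with a pseudocount of 0.1 or 1 and with quantile normalization, no filter, a log2 fold change of at least 1, a block for the replicate number, only the 6 libraries compared, and leaving out each library. Leaving out the hair follicle-rich libraries and a hair follicle covariate were added after the data were seen, as were total-count scaling and the authors' normalized counts in the macrophage set. Figures were drawn with matplotlib 3.10.9. The third macrophage library of each group carries no replicate number and was numbered by its order in the series. S100a9 is not in the macrophage table and was not analysed there. Gene positions were taken from GENCODE vM21 on mm10 and count from 1.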

Results

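Gene expression was measured in mouse skin that held implanted elastomer discs, in macrophages and in single cells. The design placed discs of PDMS or of EVADE elastomers (H50, H70 and H90) under the back skin of female C57BL/6 mice. Bulk skin had 3 libraries each of mock, PDMS and X90, the macrophages had 3 each of P90 and PDMS, and the single cell set had 1 each of Mock, PDMS and H90. The labels do not define X90 and P90 and do not give the time of sampling. Total expected counts were 16301000 to 17770100 per skin library and 17963600 to 18740100 per macrophage library. The single cell libraries held 6267 Mock cells with a median of 3936 UMIs, 5240 PDMS cells with 4778 and 4546 H90 cells with 4234. No label says that replicates came from separate mice or cultures, so the p-values measure only the spread between these samples, which may be technical.

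The first comparison asked how skin with X90 differed from skin with PDMS. Dmbt1, a secreted scavenger receptor of glandular epithelia, and Serpinb6d, a serine protease inhibitor, fell in X90. Dmbt1 (Entrez 12945, chromosome 7, 131032053 to 131121630 on mm10) had 0.03 ± 0.02 FPKM (SD, n = 3) in X90 and 9.39 ± 5.48 in PDMS, a log2 fold change of -8.29 ± 0.78 (SE, edgeR adjusted p = 0.0381). Serpinb6d (Entrez 238568, chromosome 13, 33661405 to 33671581) had 4.17 ± 1.58 FPKM in X90 and 40.0 ± 7.81 in PDMS, a log2 fold change of -3.27 ± 0.30 (edgeR adjusted p = 0.0381). Both were lower in 3 of 3 X90 libraries than in any PDMS library. The glandular keratin gene Krt18 was also higher in all 3 PDMS libraries (58.4 FPKM against 0.81 in X90 and 1.45 in mock). When the authors clustered PDMS with Mock single cells, a cluster with Krt18 held 1.98% of PDMS and 0.271% of Mock cells, and within the PDMS library Dmbt1 was highest in the cluster led by Krt18. Serpinb6d was near 0 in the single cells, at 0.000192 per 10000 UMIs in PDMS, 0.000869 in Mock and 0.0015 in H90, and did not follow the bulk direction there. Serpinb6d has similar paralogs, so its counts are uncertain where reads were shared.

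Of 15156 genes tested for X90 against PDMS, edgeR called 0 higher and 2 lower in X90, while 779 had an unadjusted p under 0.05. DESeq2 called 126 genes and limma-trend on FPKM called 2. A replicate block over the 9 skin libraries left 0 calls in edgeR, as did a fit of only the 6 compared libraries. The groups did not overlap at 1177 genes, or 7.77%, where chance gives 10%. Leaving out any 1 library other than PDMS replicate 2 ended both calls, with adjusted p up to 0.587 for Dmbt1 and for Serpinb6d. Over 20 alternatives the log2 fold change of Dmbt1 ran from -8.85 to -3.14 (limma-trend on log2(FPKM + 1)) and passed in 8, and that of Serpinb6d ran from -3.58 to -3.01 and passed in 9. Without PDMS replicate 2, 22 genes passed, 1 higher and 21 lower in X90. S100a8 and S100a9, which together form the neutrophil alarmin calprotectin, were lower in X90 but did not pass. S100a8 had 16 ± 5.66 FPKM in X90 and 109 ± 86.1 in PDMS (log2 fold change -2.80 ± 0.70, edgeR adjusted p = 0.582, lower in 3 of 3 X90 libraries than in any PDMS library). S100a9 had 9.75 ± 4.43 FPKM in X90 and 91.7 ± 89.4 in PDMS, where the 3 libraries read 181, 2.65 and 90.9 (log2 fold change -3.25 ± 1.16, edgeR adjusted p = 0.843). With DESeq2 the adjusted p was 0.00658 for S100a8 and 0.1 for S100a9.

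**Figure D1:**
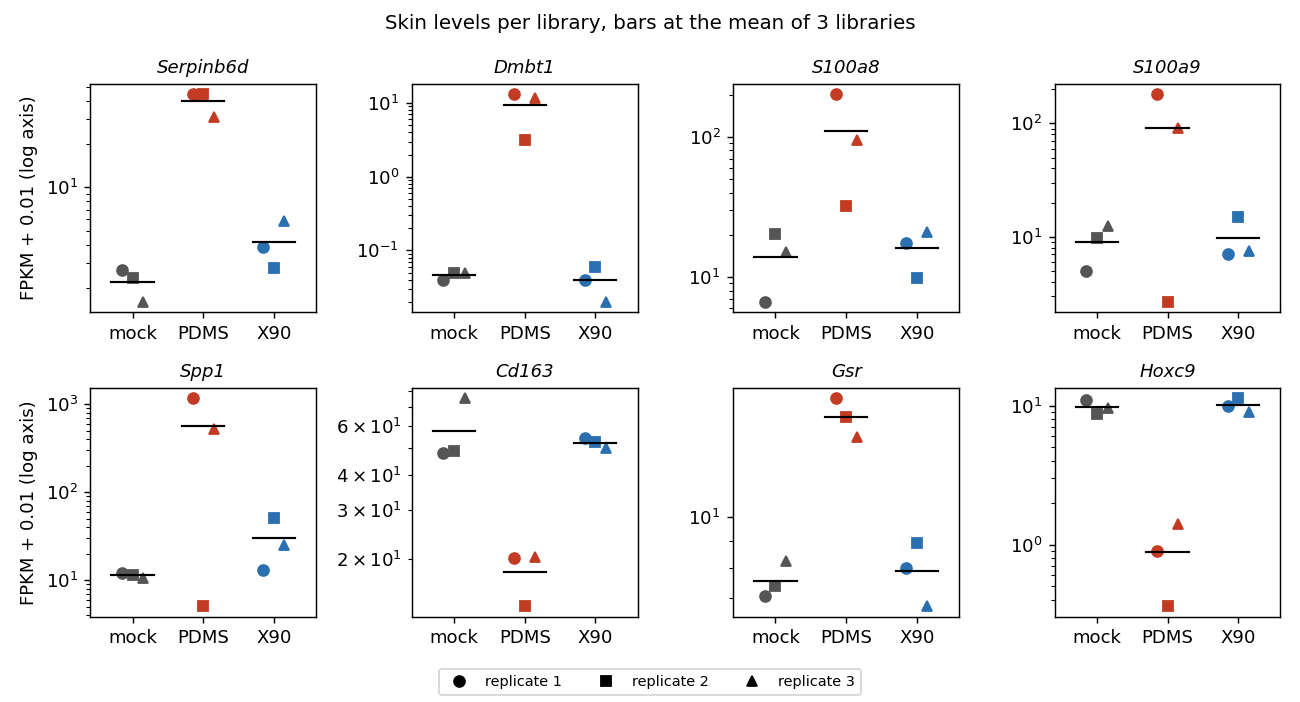
FPKM of 8 genes in each skin library on log axes, with replicate 1 as circles, replicate 2 as squares, replicate 3 as triangles and bars at the mean of 3 libraries. Serpinb6d and Dmbt1 lie above all other libraries in all 3 PDMS libraries, while S100a9 and Spp1 read 2.65 and 5.08 FPKM in PDMS replicate 2.

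Genes of the oxidative stress response, which detoxify reactive oxygen and are driven largely by NRF2, were lower in X90 than in PDMS as a group. The list's median log2 fold change was -0.72, 10 of its 12 measured members were fitted lower, and its mean lay below every PDMS library in 3 of 3 X90 libraries (camera adjusted p = 2.14e-08; adjusted p = 0.0408 with an estimated correlation). Without PDMS replicate 2 the camera adjusted p was 2.91e-06 with the preset correlation but 0.224 with an estimated one. No member passed over all genes, and 6 fell when adjusted over the list alone. Gsr, glutathione reductase, had 7.88 FPKM in X90 and 15.4 in PDMS. Slc7a11, the cystine importer, had 0.167 and 2.26, Txnrd1, thioredoxin reductase, 16.6 and 27.2, and the metallothionein Mt1 601 and 971.

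Alternative activation genes were higher in X90, with a list median of 0.97 and 14 of 15 members fitted higher (camera adjusted p = 1.70e-05, above every PDMS library in 3 of 3). Cd163, the haemoglobin scavenger receptor of resident macrophages, had 52.0 ± 2.15 FPKM in X90 and 17.9 ± 3.84 in PDMS (log2 fold change 1.52 ± 0.25, edgeR adjusted p = 0.299). Folr2, a folate receptor of resident macrophages, had 396 and 184 FPKM, the lectin Mgl2 had 196 and 100, and the cytokine Il10 had 2.47 and 1.15. Antigen presentation genes of MHC class II were higher in X90, with a median of 0.68 (11 of 12 fitted higher, camera adjusted p = 8.76e-06, above every PDMS library in 2 of 3). H2-Aa had 1801 FPKM in X90 and 1014 in PDMS, H2-DMa 85.3 and 48.9, and the costimulator Cd86 15.4 and 7.50. Adjusted p = 0.784 with an estimated correlation for both lists, and 1 and 0 members respectively changed when adjusted over the list alone.

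The neutrophil, immediate early and collagen lists were called lower in X90. The neutrophil list had a median of -1.80 with 9 of 10 members fitted lower (camera adjusted p = 0.000500), although the list means of the 2 groups overlapped. Of its members, 5 fell when adjusted over the list alone, and 0 over all genes. The granule protein Ltf had 0.05 FPKM in X90 and 1.99 in PDMS. The chemokine receptor Cxcr2 had 0.223 and 1.45, and the iron-binding Lcn2 8.32 and 35.3. Over all single cells, without replicates, the scaled mean of Ltf was 0.239 in PDMS, 0.0119 in Mock and 0.003 in H90. The glandular gene Krt18 had 1.09, 0.152 and 0.00338 in the same order. A neutrophil source of the Ltf change was therefore not separated from gland-like cells. The immediate early and heat shock list had a median of -0.41 with 12 of 13 members fitted lower (camera adjusted p = 0.000292, below every PDMS library in 3 of 3). Fos had 10.6 and 22.3 FPKM and Junb 58.9 and 102. The collagen and fibrosis list had a median of -0.33 with 25 of 29 members fitted lower (camera adjusted p = 0.000430). Its mean lay below every PDMS library in 0 of 3 X90 libraries, PDMS replicate 2 read below all 3 (7.43 log2 CPM against 7.63 to 8.30), and 0 members of this list or the immediate early list changed when adjusted over the list alone. Its smooth muscle and myofibroblast genes Acta2 and Tagln had 141 and 75.2 FPKM in X90 and 200.1 and 116 in PDMS, and the matrix genes Tnc and Col12a1 8.11 and 6.65 against 27.2 and 20.4. Adjusted p = 0.784 with an estimated correlation for these 3 lists. The collagen call was lost without PDMS replicate 1 (adjusted p = 0.283).

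A further 6 of the 12 called lists in X90 against PDMS rested on single libraries. Adjusted p = 0.784 with an estimated correlation for each, and 0 of their members changed when adjusted over the list alone. The giant cell and lipid-associated macrophage list was lower (median -0.97, camera adjusted p = 0.0109, 14 of 15 fitted lower). Its matrix protein Spp1 had 29.9 ± 19.3 FPKM in X90 and 569 ± 587 in PDMS, Gpnmb 84.8 and 274, and the osteoclast phosphatase Acp5 73.9 and 142. That call was lost without PDMS replicate 1 (0.640), PDMS replicate 3 (0.162), X90 replicate 1 (0.109) or X90 replicate 2 (0.0514). The adipocyte list was lower (median -0.66, 13 of 14 fitted lower, camera adjusted p = 0.000760), with the hormone Lep at 16.2 against 29.3 FPKM, and was lost without PDMS replicate 3 (0.304) or X90 replicate 2 (0.126). The macrophage and monocyte list was higher (median 0.41, 16 of 20 fitted higher, camera adjusted p = 0.00106), with the monocyte receptor Ccr2 at 30.6 against 15.5 FPKM. It turned direction without PDMS replicate 2 (0.541) and was lost without X90 replicate 2 (0.115). The keratinocyte list was higher (median 0.31, 10 of 15 fitted higher, camera adjusted p = 0.00473), with Krt1 at 214 against 133 FPKM, and was lost without PDMS replicate 3 (0.831) or X90 replicate 3 (0.216). The T and NK cell list was higher (median 0.35, 14 of 17 fitted higher, camera adjusted p = 0.0109) and was lost without PDMS replicate 2 (0.832) or X90 replicate 3 (0.181). The skeletal muscle list tested as higher (camera adjusted p = 0.0151) although its median of -0.04 and 11 of 15 fitted members pointed lower. It turned direction without PDMS replicate 2 (0.00307) and was lost without X90 replicate 1 (0.142). Without PDMS replicate 2 the number of called lists rose from 12 to 22.

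Inflammatory cytokine and chemokine genes did not pass as a list in X90 against PDMS (median -0.68, camera adjusted p = 0.0501). The neutrophil chemokine Cxcl2 had 0.577 FPKM in X90 and 35.7 in PDMS, the interleukin Il1b 2.88 and 25.0, and the prostaglandin synthase Ptgs2 0.527 and 2.48. The type I interferon list had an adjusted p of 0.387 and a median of 0.43.

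PDMS skin was compared with mock skin to ask which genes differed around PDMS. Serpinb6d and Dmbt1 rose. Serpinb6d had 40.0 ± 7.81 FPKM in PDMS and 2.19 ± 0.542 in mock (log2 fold change 4.17 ± 0.31, edgeR adjusted p = 0.0147, higher in 3 of 3). Dmbt1 had 9.39 ± 5.48 and 0.0367 ± 0.00577 (log2 fold change 7.91 ± 0.75, edgeR adjusted p = 0.0439, higher in 3 of 3). This comparison and that of X90 share the PDMS libraries, from which part of the 2 shared calls may come. In 20 simulations of unchanged libraries at most 0 calls were shared, but as each simulated comparison had at most 1 call this says little about sharing 2. Independent lists of this size would share 0.000264. Of 15156 genes, edgeR called 2 higher and 0 lower in PDMS than in mock, 705 had an unadjusted p under 0.05, DESeq2 called 141 and limma-trend on FPKM 1. The groups did not overlap at 1259 genes, or 8.31%, where chance gives 10%. The Dmbt1 call was lost without any 1 library other than PDMS replicate 2, with adjusted p up to 0.647. The Serpinb6d call was lost without PDMS replicate 1, X90 replicate 1 or any 1 of the mock libraries, with adjusted p up to 0.162. Over 20 alternatives Dmbt1 ran from 3.13 (limma-trend on log2(FPKM + 1)) to 8.48 and passed in 7, and Serpinb6d from 3.68 to 4.33 and passed in 13. With a replicate block over the 9 skin libraries edgeR called 0 genes, and with only the 6 compared libraries 1.

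S100a8 had 109 ± 86.1 FPKM in PDMS and 13.9 ± 6.85 in mock (log2 fold change 2.97 ± 0.70, edgeR adjusted p = 0.565, higher in 3 of 3). S100a9 had 91.7 ± 89.4 and 9.06 ± 3.83 (log2 fold change 3.36 ± 1.17, edgeR adjusted p = 0.933, higher in 2 of 3). The neutrophil list was higher in PDMS, with a median of 1.79 and 9 of 10 members fitted higher (camera adjusted p = 0.000136; adjusted p = 0.535 with an estimated correlation). Its member Ltf was also higher in PDMS than in Mock over all single cells (scaled means 0.239 and 0.0119). The glandular gene Krt18 was higher there too (1.09 and 0.152), so the Ltf change was not separated from gland-like cells. Of the list members, 5 of 10 rose when adjusted over the list alone, and 0 over all genes. Its mean log2 CPM were 4.2, 1.56 and 4.08 in the PDMS libraries and 1.66, 1.92 and 2.23 in mock, so PDMS replicate 2 lay below all mock libraries.

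Oxidative stress genes were higher in PDMS than in mock in 3 of 3 libraries (median 0.77, 10 of 12 fitted higher, camera adjusted p = 1.31e-08; adjusted p = 0.0382 with an estimated correlation). Over the list alone 8 of 12 rose, among them Gsr, Txnrd1 and Mt1, with log2 fold changes of 1.03, 0.75 and 0.75. Collagen and fibrosis genes were higher (median 0.55, 26 of 29 fitted higher, camera adjusted p = 3.31e-08, above all mock libraries in 2 of 3), with 1 member passing when adjusted over the list alone. Col8a1, a short-chain collagen of vessel walls, had 14.7 FPKM in PDMS and 1.32 in mock, Tagln 116 and 64.7, and Acta2 200.1 and 129.6. The giant cell and lipid-associated macrophage list was higher (median 1.80, 14 of 15 fitted higher, camera adjusted p = 1.02e-06), with 5 members passing over the list alone, above all mock libraries in 2 of 3 and below them in PDMS replicate 2. Spp1 had 569 FPKM in PDMS and 11.4 in mock, the elastase Mmp12 391 ± 375 and 6.52, Gpnmb 274 and 26.1, and the proton pump subunit Atp6v0d2 24.7 and 1.63. Immediate early genes were higher (median 0.41, 12 of 13 fitted higher, camera adjusted p = 8.58e-05, above all mock libraries in 2 of 3), with Fos at 22.3 against 8.25 FPKM. Adjusted p = 0.535 with an estimated correlation for the collagen, giant cell and immediate early lists.

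Antigen presentation and alternative activation genes were lower in PDMS than in mock. The MHC class II list had a median of -0.89 (10 of 12 fitted lower, camera adjusted p = 3.40e-08, below all mock libraries in 1 of 3), and 2 members passed when adjusted over the list alone. H2-DMa had 48.9 FPKM in PDMS and 115 in mock and Cd86 7.50 and 15.2. The alternative activation list had a median of -0.79 (13 of 15 fitted lower, camera adjusted p = 1.80e-05, below all mock libraries in 3 of 3), and 1 member passed over the list alone. Cd163 had 17.9 and 57.2 FPKM, Folr2 184 and 412, the resistin-like Retnla 1298 and 7470.1 and the lectin Clec10a 95.9 and 189.8. Adjusted p = 0.535 with an estimated correlation for both lists.

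The other 9 called lists in PDMS against mock depended on single libraries. The cytokine and chemokine list was higher (median 0.80, camera adjusted p = 0.00789; adjusted p = 0.795 with an estimated correlation), with 8 of 20 members higher when adjusted over the list alone. Cxcl2 had 35.7 FPKM in PDMS and 0.0467 in mock, Cxcl3 19.9 and 0.0800, and the macrophage chemokine Ccl3 27.8 and 0.707. It was lost without PDMS replicate 1 (0.311) or PDMS replicate 3 (0.0948). The mast cell list was higher (median 0.55, camera adjusted p = 0.00302; adjusted p = 0.708 with an estimated correlation), with the stem cell factor receptor Kit at 6.68 against 3.83 FPKM and 1 member passing over the list alone. It was lost without PDMS replicate 1 (0.208), PDMS replicate 3 (0.127) or mock replicate 2 (0.0985). The T and NK cell list was lower (median -0.47, camera adjusted p = 0.00246; adjusted p = 0.708 with an estimated correlation) and was lost without PDMS replicate 2 (0.801) or mock replicate 3 (0.179). The macrophage and monocyte list tested as lower (median -0.25, camera adjusted p = 0.00169; adjusted p = 0.795 with an estimated correlation) while its mean was 0.05, and it turned direction without PDMS replicate 2 (0.244). The skeletal muscle list was lower (median -0.41, camera adjusted p = 4.19e-05; adjusted p = 0.708 with an estimated correlation) and turned direction without PDMS replicate 2 (0.801). The lipid efflux list was lower (median -0.19, camera adjusted p = 0.0293; adjusted p = 0.708 with an estimated correlation). It turned direction without PDMS replicate 2 (0.826) and was lost without mock replicate 3 (0.249).

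The keratinocyte list was lower in PDMS than in mock (median -0.13, camera adjusted p = 0.00811; adjusted p = 0.795 with an estimated correlation). It turned direction without PDMS replicate 3 (0.891) and was lost without PDMS replicate 1 (0.0661) or mock replicate 2 (0.0747). The adipocyte list was higher (median 0.50, camera adjusted p = 0.0276; adjusted p = 0.798 with an estimated correlation). It turned direction without PDMS replicate 3 (0.882) and was lost without PDMS replicate 1 (0.0649), mock replicate 2 (0.575), X90 replicate 2 (0.0590) or X90 replicate 3 (0.0502). The complement list was lower (median -0.05, camera adjusted p = 0.0495; adjusted p = 0.853 with an estimated correlation). It turned direction without PDMS replicate 2 (0.0762) and was lost without X90 replicates 1, 2 and 3 in turn (0.137, 0.0638 and 0.160), mock replicate 1 (0.267) or mock replicate 3 (0.484).

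X90 skin was compared with mock skin to ask which genes differed around X90. The giant cell and lipid-associated macrophage list was higher in X90, above all mock libraries in 3 of 3, with a median of 0.70 and 13 of 15 members fitted higher (camera adjusted p = 0.000508; adjusted p = 0.979 with an estimated correlation). Mmp12 had 102 FPKM in X90 and 6.52 in mock, Gpnmb 84.8 and 26.1 and Atp6v0d2 9.87 and 1.63. Collagen and fibrosis genes were higher in 2 of 3 libraries (median 0.23, 26 of 29 fitted higher, camera adjusted p = 0.000976; adjusted p = 0.979 with an estimated correlation). Col8a1 had 3.85 FPKM in X90 and 1.32 in mock, and Aspn, a small matrix proteoglycan, 72.2 and 49.1. The giant cell call was lost without X90 replicate 3 (0.0595) or mock replicate 2 (0.0700), and the collagen call without X90 replicate 2 (0.846) or mock replicate 3 (0.0570). S100a8 and S100a9 had log2 fold changes of 0.17 ± 0.68 and 0.10 ± 1.11 (edgeR adjusted p = 1 for both).

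Of 15156 genes, edgeR called 0 between X90 and mock, 46 had an unadjusted p under 0.05, and DESeq2 and limma-trend on FPKM called 0 each. The groups did not overlap at 530 genes, or 3.50%, where chance gives 10%. On simulated data of this size edgeR recovered 56.7% of genes changed 4-fold. That simulation held 200 changed genes, which eases the adjusted threshold, so recovery would be lower where few genes change. Of the 5 called lists, the mast cell list was higher (median 0.23, camera adjusted p = 0.0126), with the IgE receptor Fcer1a at 2.03 against 0.903 FPKM. It was lost without X90 replicate 3 (0.140), mock replicate 1 (0.0623) or mock replicate 2 (0.411). The hypoxia and glycolysis list was lower (median -0.15, camera adjusted p = 0.0126), with the glycolysis regulator Pfkfb3 at 20.9 against 25.7 FPKM, and was lost without X90 replicate 3 (0.206), mock replicate 1 (0.0753) or mock replicate 3 (0.0897). The skeletal muscle list was lower (median -0.48, camera adjusted p = 0.0182) and was lost without X90 replicate 2 (0.316), X90 replicate 3 (0.226), mock replicate 1 (0.0919) or mock replicate 3 (0.112). Adjusted p = 0.979 with an estimated correlation for these 3 lists, and in all 5 called lists 0 members changed when adjusted over the list alone. Leaving out single libraries moved the number of called lists by over 1.5 times: to 8 without PDMS replicate 2 or mock replicate 2, 10 without X90 replicate 1, 9 without X90 replicate 2 and 3 without X90 replicate 3 or mock replicate 3. The lists for NF-kB targets, type I interferon response, B and plasma cells, hair follicle, fibroblast, endothelial, pericyte, Schwann, melanocyte and red blood cells, cell cycle, cholesterol synthesis and adhesion passed in none of the 3 skin comparisons. Their lowest adjusted p was 0.0822, for pericytes in PDMS against mock.

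PDMS replicate 2 stood apart from the other PDMS libraries. Its hair follicle list had the highest mean of all 9, at 9.44 log2 CPM, against 7.98 in mock replicate 2, 6.3 in X90 replicate 1 and 1.01 to 3.05 in the others. The 109 keratin and keratin-associated genes took 5.36% of its counts, 2.6% in mock replicate 2 and 0.539% to 1.73% in the others. PDMS replicate 2 also had the lowest skeletal muscle mean, 5.53 log2 CPM against 9.5 to 11 in the others. Its fibroblast (8.43) and endothelial (4.92) means were the lowest as well, so its mix of tissue differed. Myeloid genes read lower in it than in the other PDMS libraries: Spp1 read 1176, 5.08 and 526 FPKM in PDMS replicates 1, 2 and 3, Mmp12 751, 3.32 and 418, and the macrophage lysozyme Lyz2 4645, 548 and 3568. Without it, 83 genes passed between PDMS and mock, 81 higher and 2 lower. Those with the smallest adjusted p were Dmbt1 (log2 fold change 8.34, edgeR adjusted p = 0.000204) and Slpi (4.00, adjusted p = 0.00472), and Wfdc2 (8.02) passed too. Among the 83 were also S100a9 (log2 fold change 3.93, edgeR adjusted p = 0.0237), S100a8 (3.42, adjusted p = 0.0374), Mmp12 (6.54) and Spp1 (6.25). Ccl3 (5.89), Il1b (4.09), Gpnmb (3.90) and Tnf (2.49) passed as well. So did Cxcl2, which read 68.9 and 38.3 FPKM in PDMS replicates 1 and 3 and at most 0.07 in mock. Between X90 and PDMS, Dmbt1 (-8.73) and Slpi (-3.85) had the smallest adjusted p, and only Hoxc9 (3.08) was higher in X90. The 21 lower genes included Wfdc2 (-8.02), Cxcl2 (-6.56), Spp1 (-4.87), Ccl3 (-4.12), S100a9 (-3.84, adjusted p = 0.0476), Il1b (-3.72) and Tnf (-2.32). S100a8 did not pass (-3.26, adjusted p = 0.0679). Mock replicate 2 and X90 replicate 1, also hair follicle-rich, stayed in these fits. With the hair follicle-rich library left out of each group, 17 genes passed between PDMS and mock and 1 between X90 and PDMS. S100a8 and S100a9 did not pass there (edgeR adjusted p = 0.123 and 0.109 against mock, 0.192 and 0.191 for X90 against PDMS).

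Of 29 tested Hox genes, the transcription factors that encode position along the body axis, 9 were lower and 3 higher in all 3 PDMS libraries than in the other 6 libraries, where chance gives 2.38% of genes in either direction. Hoxc9 read 0.890, 0.35 and 1.39 FPKM in the PDMS libraries and 8.69 to 11.3 in the others (log2 fold change to mock -3.45). Hoxc10 had 2 counts in all PDMS libraries and 300 in mock, a ratio of mock to PDMS of 152 per total count (exact 95% counting interval 41.7 to 1260.5). The log2 fold change to mock was -2.22 for Hoxb9, 1.06 for Hoxb4 and 0.90 for Hoxc4, and no Hox gene passed in the fit of all libraries (lowest edgeR adjusted p = 0.197). Without PDMS replicate 2, Hoxc9 (-3.04), Hoxb4 (1.04) and Hoxc4 (0.95) passed. The keratin gene Krt18, chosen after its values were seen, did not pass against mock (edgeR adjusted p = 0.454) and read 21.0, 31.9 and 122 FPKM in the PDMS libraries and at most 3.63 in the others. The milk protein gene Csn3 had a mean of 15.3 FPKM in PDMS, 0.140 in X90 and 0.72 in mock, and did not pass against mock (edgeR adjusted p = 0.882). Plet1 and Wfdc18 also lead the PDMS single cell cluster with Krt18 and Csn3. Their bulk log2 fold changes to mock, -0.15 ± 0.70 and 0.57 ± 0.77, had errors too wide to tell a rise from none. Wfdc2, at 0.128 per 10000 UMIs over all PDMS single cells and 0.0334 in Mock, passed against mock without PDMS replicate 2 (8.02). In the single cell PDMS library Dmbt1 was highest in the 105 cells of a cluster led by Krt18 (29.2 per 10000 UMIs) and Csn3 (25.7), at 0.271, and at most 0.0450 in every other PDMS cluster.

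**Figure D2:**
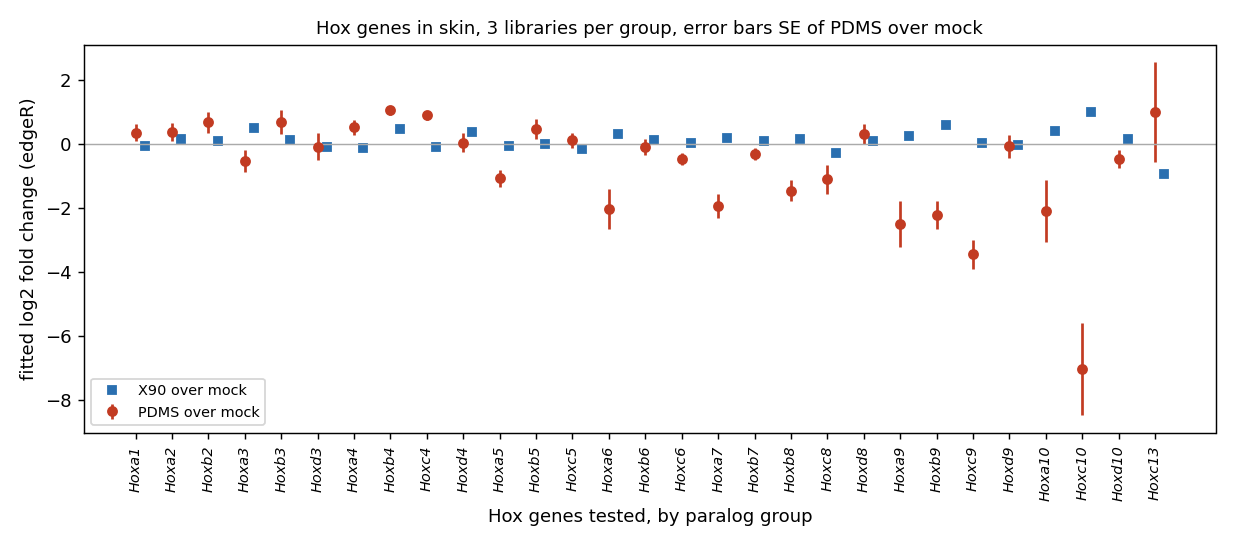
Fitted log2 fold change of 29 Hox genes in skin, ordered by paralog group, for PDMS over mock (circles, SE bars) and X90 over mock (squares). Several genes of groups 7 to 10 lie below 0 in PDMS, with Hoxc9 at -3.45, while Hoxb4 and Hoxc4 lie at 1.06 and 0.90.

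The macrophage comparison asked how cells labelled P90 differed from cells labelled PDMS. Genes of the oxidative stress response rose in P90 while genes of the cell cycle and of cholesterol synthesis fell. Hmox1, haem oxygenase 1 (chromosome 8, 75093621 to 75100589), rose from 211 ± 11 FPKM in PDMS to 8449 ± 762 in P90 (log2 fold change 5.69 ± 0.15). S100a8 rose from 0.290 ± 0.252 to 122 ± 26.9 FPKM (log2 fold change 8.89 ± 0.40, edgeR adjusted p = 6.92e-08, higher in 3 of 3). With 897 counts in P90 and 2 in PDMS, the ratio per total count was 444 with an exact 95% counting interval of 123 to 3674. S100a9 is not in this table.

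Of 11031 tested genes, edgeR called 3776 higher and 4162 lower in P90, or 72.0% of all. The groups did not overlap at 8304 genes, or 75.3%, where chance gives 10%. The balance of directions depended on the scaling: with total counts, 2464 rose and 5566 fell, and the median log2 fold change of all genes was -0.42 against -0.06 with TMM. At a log2 fold change of at least 1, 4257 genes passed. Changes below are relative to TMM scaling, and the medians named for cell cycle, cholesterol, oxidative stress, neutrophil and interferon lists kept their sign under total counts, DESeq2 size factors and the authors' normalized counts.

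Cell cycle genes fell in P90, 17 of 18 with 1 not passing (median -5.75, camera adjusted p = 1.21e-08; adjusted p = 0.172 with an estimated correlation). The cyclin Ccna2 had 0.367 FPKM in P90 and 54.9 in PDMS, the ribonucleotide reductase Rrm2 0.677 and 72.6, the mitotic kinase Plk1 0.820 and 80.0 and the survivin gene Birc5 2.04 and 147. Cholesterol synthesis genes fell, 15 of 16 with 1 rising (median -2.24, camera adjusted p = 6.95e-06; adjusted p = 0.121 with an estimated correlation). The squalene epoxidase Sqle had 8.09 FPKM in P90 and 50.9 in PDMS, and the regulator Srebf2 22.1 and 127. Type I interferon genes fell, 10 of 11 with 1 rising (median -1.09, camera adjusted p = 0.0128; adjusted p = 0.172 with an estimated correlation), among them the RNA sensor Ddx58 (log2 fold change -2.53). Adjusted over the list alone, 17, 16 and 11 members of these 3 lists changed.

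Oxidative stress genes rose in P90, all 12 of 12 (median 3.71, camera adjusted p = 3.29e-06; adjusted p = 0.121 with an estimated correlation). Beside Hmox1, the glutathione synthesis subunit Gclm had 718 FPKM in P90 and 23.5 in PDMS, sulfiredoxin Srxn1 530.3 and 19.2, and Slc7a11 62.9 and 2.95. Immediate early and heat shock genes rose, 11 of 12 with 1 falling (median 1.53, camera adjusted p = 0.000351; adjusted p = 0.121 with an estimated correlation). The phosphatase Dusp1 had 242 and 10.6 FPKM and the heat shock protein Hspa1b 31.1 and 2.96. Macrophage and monocyte genes rose, 11 of 14 with 2 falling (median 1.14, camera adjusted p = 0.00513; adjusted p = 0.172 with an estimated correlation), with the lectin Clec4d at 2961 against 74.8 FPKM, the lipopolysaccharide co-receptor Cd14 at 4712 against 611 and the antibody receptor Fcgr3 at 291 against 12.4. Adjusted over the list alone, 12, 12 and 13 members of these 3 lists changed.

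The neutrophil list rose in P90, 5 of 6 with 1 falling (median 4.18, camera adjusted p = 0.0132; adjusted p = 0.172 with an estimated correlation). The receptor Trem1 had 22.9 FPKM in P90 and was listed at 0 in PDMS, Lcn2 had 5.72 and 0.0933 FPKM, and the growth factor receptor Csf3r fell by 3.94 on the log2 scale. Giant cell and lipid-associated macrophage genes rose, 11 of 15 with 3 falling (median 1.07, camera adjusted p = 0.0129; adjusted p = 0.426 with an estimated correlation). Gpnmb had 159 and 2.07 FPKM and Acp5 207 and 8.58, while lipoprotein lipase, Lpl, had 1.05 and 259. Adhesion and cytoskeleton genes rose, 8 of 14 with 2 falling (median 0.70, camera adjusted p = 0.0452; adjusted p = 0.175 with an estimated correlation), with zyxin, Zyx, at 101 against 16.9 FPKM. The adhesion call was lost without PDMS replicate 3 (adjusted p = 0.0517). Adjusted over the list alone, 6, 14 and 10 members of these 3 lists changed. In each of the 9 called lists as many members changed over all genes as over the list alone.

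**Figure D3:**
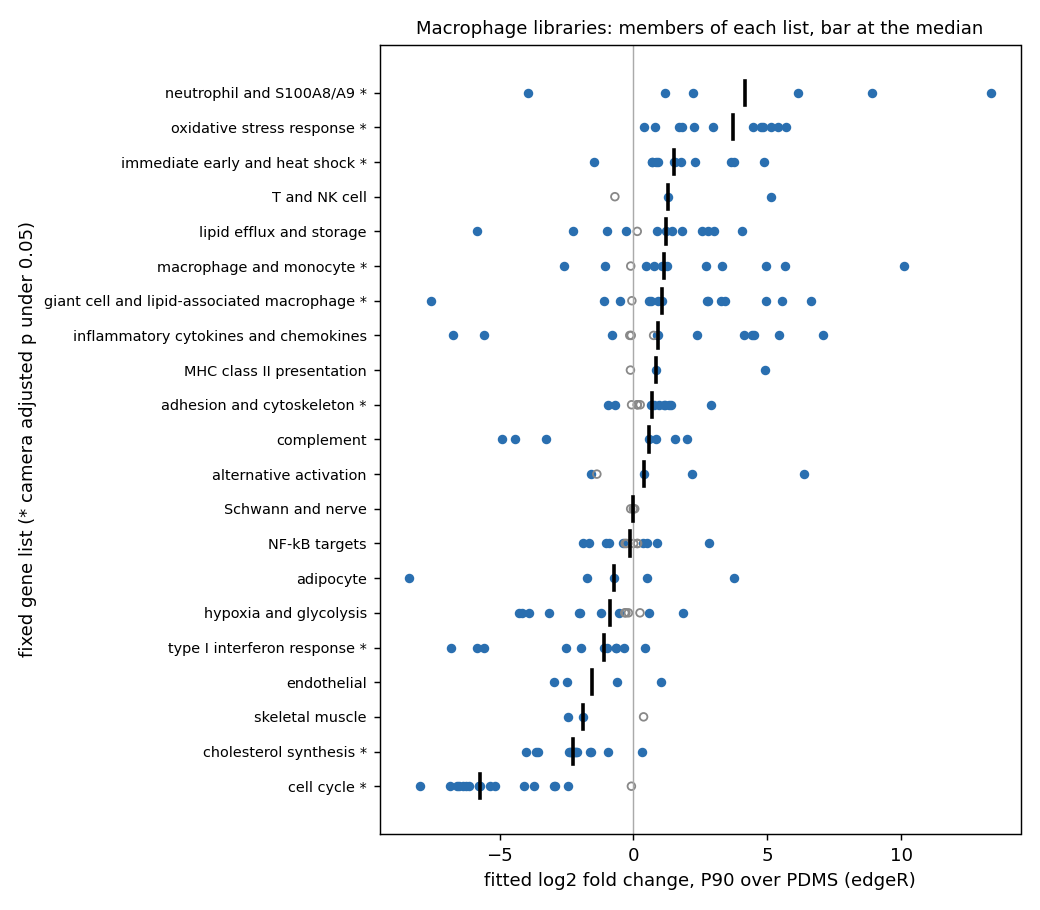
Fitted log2 fold change of P90 over PDMS for the members of 21 gene lists in macrophages, with filled points for members past the test, open points for the rest and bars at list medians. The cell cycle median lies at -5.75 and that of the oxidative stress list at 3.71.

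The other 12 of 21 macrophage lists did not pass, although many of their members changed. Cytokine and chemokine genes had 8 rising and 3 falling of 14 (camera adjusted p = 0.0733), with oncostatin M, Osm, at 59.5 against 3.57 FPKM, Il1b at 19.9 against 0.183, Cxcl2 at 104 against 6.00 and Nos2, inducible nitric oxide synthase, at 0.0733 against 4.11. Hypoxia and glycolysis genes had 2 rising and 8 falling of 14 (0.0511), with Bnip3 at 28.6 against 333 FPKM and Adm, adrenomedullin, at 1.78 against 44.6. Lipid efflux and storage genes had 8 rising and 4 falling of 13 (0.102), with the droplet protein Plin2 at 843 against 64.6 FPKM and the transfer protein Pltp at 0.9 against 66.0. NF-kB targets had 4 rising and 5 falling of 14 (0.899), and complement genes had a median of 0.59 but a mean of -1.09 (0.966). Alternative activation (0.545), MHC class II (0.207), T and NK cell (0.207), adipocyte (0.452), skeletal muscle (0.276), endothelial (0.276) and Schwann cell lists (0.966) had few measured members.

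Several of the largest rises by the fixed rule were in genes near 0 in PDMS. Trem1, Eml1 (3.43 FPKM in P90), Sstr5 (4.67), Gsta3 (9.28) and Ramp3 (7.67) were listed at 0 in PDMS, and Il1f9 had 134 against 0.0667 FPKM, the lectin Clec4n 458 against 0.437, Treml4 71.2 against 0.02 and Clcf1 16.5 against 0.01. Among the largest falls, Odf3l1 (24.6 FPKM in PDMS), the deacetylase Hdac9 (3.71), Depdc1a (3.18), the cytokine subunit Il27 (2.96), Xkr5 (1.94) and Tox2 (1.05) were listed at 0 in P90. Selenbp1 had 0.280 against 265 FPKM, Selenbp2 0.0367 against 26.6, the desaturase Scd1 0.0833 against 36.4 and the kinesin Kif15 0.00667 against 4.50. Selenbp1 and Selenbp2 are near-identical, so their counts are uncertain.

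The single cell libraries asked which cells were present in Mock, PDMS and H90 tissue, with 1 library each and no replicate check. Fibroblast-like cells made up 20.6% of Mock cells (95% exact interval 19.6 to 21.6), 44.8% of PDMS cells (43.4 to 46.1) and 38.0% of H90 cells (36.6 to 39.4). A fibroblast-like cluster led by the chemokine Cxcl5, the protease inhibitor Timp1 and the matrix gene Tnc held 1.44% of Mock (1.16 to 1.76), 9.26% of PDMS (8.48 to 10.1) and 5.76% of H90 cells (5.10 to 6.48). A second, led by the acute phase gene Saa3 and the protease Mmp3, held 3.54%, 7.88% and 10.2%. T cell-like cells of a cluster with the gamma-delta receptor gene Trdc held 6.94% of Mock (6.32 to 7.60), 0.840% of PDMS (0.611 to 1.13) and 7.83% of H90 cells (7.07 to 8.65). This pooled cluster is not all T cells. In the libraries' own clusterings, T cell-like clusters, which differed in kind, held 488 Mock, 496 PDMS and 361 H90 cells. Keratinocyte-like cells held 7.15%, 0.725% and 1.67%, and pericyte-like cells 0.112%, 0.515% and 1.65%. Clusters that no marker class named held 65.2%, 53.1% and 50.8%.

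**Figure D4:**
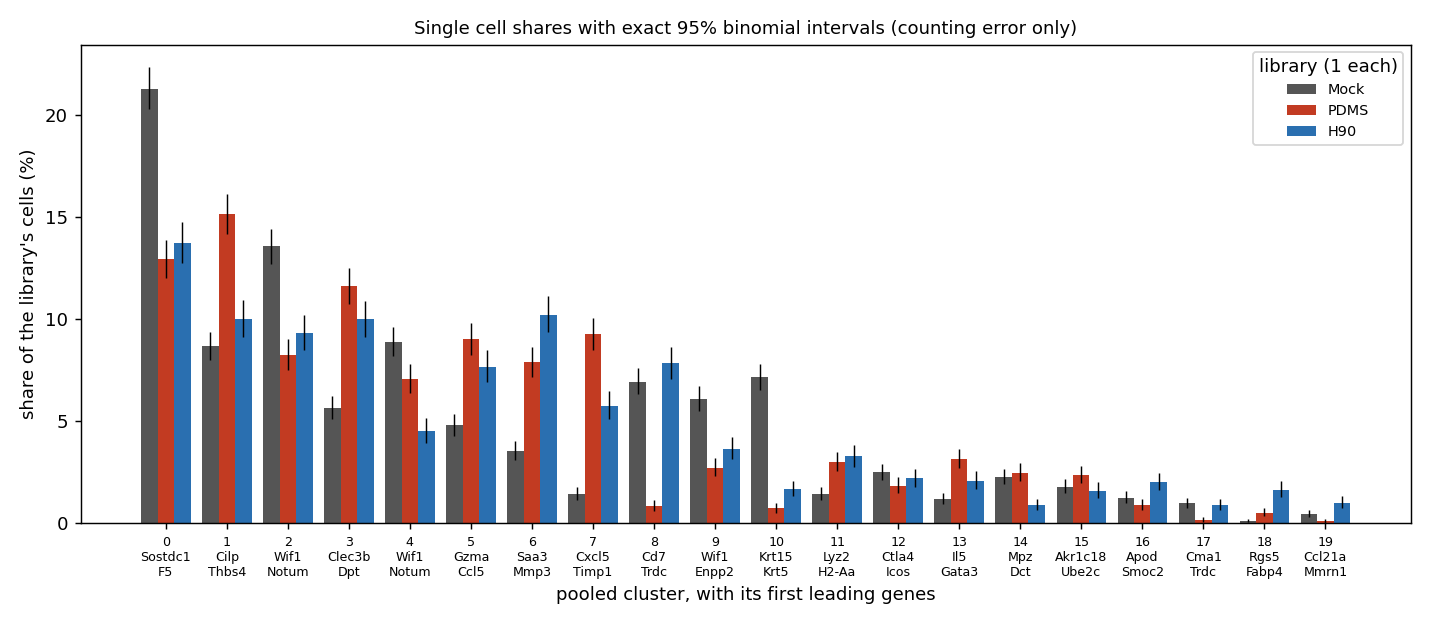
Share of each single cell library's cells in 20 pooled clusters, in percent, with bars for Mock, PDMS and H90 (1 library each) and exact 95% binomial intervals for counting error. The T cell-like cluster with Trdc, which is not all T cells, holds 6.94%, 0.840% and 7.83%. The Cxcl5 and Timp1 cluster holds 1.44%, 9.26% and 5.76%.

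Myeloid cells of a cluster led by Lyz2, H2-Aa and Cd74 made up 1.44% of Mock (1.16 to 1.76), 3.02% of PDMS (2.57 to 3.51) and 3.28% of H90 cells (2.78 to 3.84). In the libraries' own clusterings, S100a8 in the unnamed cluster with Lyz2 and Cd74 had 3.50 per 10000 UMIs in H90 (150 cells) and 1.83 in PDMS (160 cells), and S100a9 12.9 and 5.56. Il1b had 23 in H90, 7.95 in PDMS and 13.6 in the dendritic cell-like cluster of Mock (86 cells). These clusters differ in their mix of cells: C1qa, a complement gene of macrophages, had 7.18, 19.1 and 1.17 in the same order, and Ccr7 and Ccl22 were among the leading genes in PDMS and S100a9 and Alox5ap in H90, so the differences were not separated from the mix. Over all cells S100a8 had 0.0434 per 10000 UMIs in Mock, 0.0707 in PDMS and 0.144 in H90, and S100a9 0.000147, 0.159 and 0.371. Saa3 had 0.0543, 11.9 and 32.2, Timp1 0.278, 5.21 and 5.36, and Spp1 0.610, 2.02 and 0.874 in the same order. Median mitochondrial UMIs were 3.22%, 1.56% and 2.35%.

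Within fibroblast-like cells, the collagenase Mmp13 had 1.16 per 10000 UMIs in H90 and 0.0484 in PDMS, the extracellular protein gene Coch 1.62 and 0.0695, the B cell chemokine Cxcl13 0.686 and 0.111 and the dehydrogenase Adh7 0.516 and 0.118. Lower in H90 were the matrix genes Hmcn2 (0.127 against 2.6) and Thbs4 (0.974 against 6.85), Myoc (0.852 against 5.84) and the prolactin family gene Prl8a1 (0.183 against 1.36). The class is made of 5 clusters in each library that are not the same, and the largest in PDMS, with 852 of its 2335 cells, is led by Cilp, Thbs4, Myoc and Hmcn2, so the mix of clusters was not separated from changes within cells. In NK and innate lymphoid-like cells (88 in H90 and 116 in PDMS), Cpxm2 had 3.40 and 0.0924. The lysosomal lipase Lipa had 0.548 and 0.0163, while Nampt had 0.0394 and 0.985. The lower means lie near 0 in few cells, so the size of these differences is uncertain. The mix of cells in this class was not separated from changes within cells. Xylb in H90 and Ttll5 in PDMS, the largest differences in fibroblast-like cells (2.89 against 0.0213 and 0.131 against 7.99), were high in every cluster of their library. The keratinocyte-like and T cell-like clusters of the separate clusterings held different kinds of cells in H90 and PDMS and were not compared.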

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

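The 4 values here, for S100a8 and the oxidative stress response list, were picked by name and not by a screen of all lists. The S100a8 fits were planned, apart from the hair follicle alternatives. Tests of the Hox, macrophage and single cell patterns below were chosen after those patterns were seen.

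S100a8 read lower in X90 skin, where it did not pass, and rose in P90 macrophages. Its log2 fold change was -2.80 in skin (X90 against PDMS, edgeR adjusted p = 0.582, 1 of 20 alternatives passing, lower in 3 of 3 X90 libraries) and 8.89 in macrophages (P90 against PDMS, higher in 3 of 3), where PDMS held 2 counts. Over all single cells it had 0.144 per 10000 UMIs in H90 and 0.0707 in PDMS, in 1 library each. The oxidative stress response list went in opposite directions, with a median log2 fold change of -0.72 in skin and 3.71 in macrophages. The neutrophil list did so too (-1.80 and 4.18), as did the giant cell and immediate early lists. The difference between the sets was not tested. The systems differ, and the labels do not say whether X90 and P90 are the same material.

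Of 29 Hox genes, 12 separated all 3 PDMS skin libraries from the other 6, as did the called gene Dmbt1 and the glandular gene Krt18, and whether these share a cause was not tested. Fewer Hox-expressing cells in PDMS would lower all such genes, but 3 Hox genes were higher in all 3 PDMS libraries while 9 were lower. Skin from another body position stays open. Of 10 separating Hox genes read in the single cells, 7 (70%) went the same way in PDMS against Mock over all cells (exact one-sided sign test p = 0.172, genes not independent). Hoxb7, Hoxb8 and Hoxb9 went the other way, at low scaled means in PDMS (0.0566, 0.0425 and 0.0214, where the cutoff was 0.02). Means over all cells also mix cell types. Within fibroblast-like cells the 7 genes kept their direction, and Hoxb9 was lower in PDMS (0.00298 against 0.0112 in Mock). Hoxb7 and Hoxb8 stayed higher there (0.0554 against 0.0306 and 0.0135 against 0.0046), and these values are low too. The median single cell log2 ratio of PDMS to Mock was -3.13 over Hox groups 9 and 10 (0.24 for H90) but -0.34 over groups 1 to 4, where the bulk median was 0.45, and the correlation of log2 fold change with paralog group was -0.558 in bulk and -0.171 in single cells. A response to PDMS stays open as well, because 12 of 29 Hox genes had an unadjusted p under 0.05 in PDMS against mock and 1 in X90 against mock, which a position would give as well.

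The macrophage libraries differed at most genes. Scaling alone is too small for the cell cycle list, whose median stayed at -5.72 or lower under 4 scalings. The factors ran only from 0.835 to 1.22, so no other outcome was possible for this list. The balance of directions did move, from 47.6% of called genes rising with TMM to 30.7% with total counts. RNA of non-myeloid cells in P90 is argued against by 9 abundant markers chosen for the test, of which Cd79a was the highest at 0.22 FPKM and Col1a1 had 0.00333. Among the other list genes Gsn had 201 FPKM in P90 but 573 in PDMS, and RNA of other myeloid cells was not tested. A response to P90 could account for the 75.3% of genes whose groups did not overlap, but a difference between culture batches follows the same groups and cannot be told apart from it.

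In each single cell library some genes, 5 in Mock, 1 in PDMS and 1 in H90, were high in every cluster and near 0 in the other libraries. Ttll5 had 4.8 to 14.5 per 10000 UMIs in the 15 PDMS clusters and at most 0.426 elsewhere, and Xylb 2.42 to 5.82 in H90 and at most 0.0803 elsewhere. The ratio of the highest to the lowest cluster mean was at most 3.01 for both genes and 1.60 to 7.39 for the 5 in Mock, with Apol7b highest. These ratios argue against free RNA of 1 cell type that formed a cluster here. Free RNA of cells that were not captured as a cluster stays open, because it would give even means as well. A response of the tissue to PDMS is argued against by bulk skin, where the Ttll5 log2 fold change of PDMS against mock was 0.15 ± 0.14 (SE). An error or a variant of 1 library or animal may account for it and stays open, since each group had 1 library.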

How the results depend on the processing

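The 2 hair follicle alternatives were added after the data were seen, and the cause was not tested for any change below. In X90 against PDMS, where 2 genes were called, DESeq2 called 126, quantile-normalized FPKM 1, the 6 compared libraries alone 0 (edgeR, 540 at an unadjusted p under 0.05), leaving out the hair follicle-rich libraries 1 and the hair follicle covariate 10, and leaving out 1 library gave 0 to 22. In PDMS against mock, with 2 called, DESeq2 called 141, FPKM 1, quantile-normalized FPKM 1, the 6 compared libraries alone 1 and leaving out the hair follicle-rich libraries 17, and leaving out 1 library gave 0 to 83. In X90 against mock, with 0 called by edgeR and 46 at an unadjusted p under 0.05, the covariate gave 3, DESeq2 and limma-trend gave 0, and each of the 9 fits without 1 library gave 0. The macrophage count fell from 7938 to 4257 at a log2 fold change of at least 1, by construction, and was 7238 to 8554 without 1 library.

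Called lists numbered 12 in X90 against PDMS, 16 in PDMS against mock, 5 in X90 against mock and 9 in macrophages. An estimated correlation left 1, 1, 0 and 0, and fry called 1, 1, 0 and 19. Without the hair follicle-rich libraries 21 lists passed in X90 against PDMS and 13 in X90 against mock. Leaving out 1 library gave 11 to 22, 13 to 21, 3 to 10 and 9 to 11 lists. Without the hair follicle-rich libraries, 4 lists reversed: macrophage (adjusted p = 0.929) and skeletal muscle (9.47e-06) in X90 against PDMS, and macrophage (0.989) and complement (0.535) in PDMS against mock. Some lists reversed without 1 library. Over these fits the adjusted p in X90 against PDMS ran from 1.85e-06 to 0.541 for macrophage and from 5.12e-07 to 0.142 for skeletal muscle. In PDMS against mock it ran from 2.20e-06 to 0.244 for macrophage, from 0.000284 to 0.484 for complement, from 4.33e-07 to 0.891 for keratinocyte, from 8.80e-05 to 0.882 for adipocyte, from 4.74e-10 to 0.801 for skeletal muscle and from 0.00396 to 0.826 for lipid efflux.

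With a replicate block over the 9 skin libraries, edgeR called 0 genes in X90 against PDMS and 0 in PDMS against mock (916 and 853 at an unadjusted p under 0.05), and in macrophages the block on the 4 numbered libraries gave 7829 genes. The block also ended the calls of the complement list in PDMS against mock (adjusted p = 0.0608) and of the adhesion list in macrophages (0.0568). It called 14 lists in X90 against PDMS, 16 in PDMS against mock and 7 in X90 against mock, of which 12, 15 and 5 were called without the block. The numbers are not known to pair the samples. Same-number skin libraries deviated with correlations of -0.489 to 0.763, with 4 of 9 over 0.1. Same-number PDMS and mock libraries all lay at 0.552 to 0.763, but PDMS replicate 1 and mock replicate 3 also had 0.570. Same-number macrophage libraries deviated with correlations of 0.0166 to 0.473, with 2 of 3 over 0.1.

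S100a8 in X90 against PDMS ran from -3.31 to -2.04 over 20 alternatives and passed in 1, and S100a9 from -3.84 to -1.94 and passed in 1. In PDMS against mock S100a8 ran from 2.21 to 3.73 and passed in 2, and S100a9 from 2.04 to 3.95 and passed in 1. S100a8 in macrophages passed in 16 of 16, from 6.58 to 9.26. Requiring at least 500 genes per cell kept 16048 of 16053 cells, too small a change to test the single cell shares. Other clustering resolutions and thinning of cells were not run, because no counts per gene and cell were used here, and leaving out neutrophils or red blood cells was not run, because no cluster carried those names.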

Other observations

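The tests of other splits were chosen before the data were examined, and the genes and cell clusters in the next 2 paragraphs were chosen after their values were seen.

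Awat2, Scd3 and Cd209f, chosen after their values were seen, were lower in all 3 PDMS skin libraries than in the other 6, and none passed. Awat2, an acyltransferase of sebum wax esters, had 15.7 ± 3.55 FPKM in PDMS, 86.7 in X90 and 53.4 in mock, and the desaturase Scd3 had 31.6, 177 and 126. The log2 fold change of Awat2 in X90 against PDMS was 2.43 ± 0.34 (edgeR adjusted p = 0.278, higher in 3 of 3). The lectin Cd209f had 107 ± 12 FPKM in PDMS, 273 in X90 and 322 in mock (log2 fold change 1.34 ± 0.23 in X90 against PDMS, edgeR adjusted p = 0.299, higher in 3 of 3). In the macrophages, the ferritin genes Fth1 and Ftl1, which store iron, rose from 3438 and 6417 FPKM in PDMS to 18292 and 36243 in P90, with log2 fold changes of 2.79 ± 0.15 and 2.87 ± 0.20. The tumour necrosis factor gene Tnf fell from 77.6 ± 5.02 to 34.1 ± 1.69 FPKM (edgeR adjusted p = 0.000181, lower in 3 of 3).

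Some single cell clusters that no marker class named differed in share between the libraries. Cells with Gzma, Ccl5 and Ifng, genes of cytotoxic lymphocytes, held 4.8% of Mock, 9.03% of PDMS and 7.66% of H90 cells. Cells with Il5 and Gata3, genes of type 2 lymphocytes, held 1.2%, 3.15% and 2.09%. Cells with the lymphatic chemokine Ccl21a held 0.431%, 0.0954% and 1.01%, and cells with Sostdc1 and Rspo3 21.3%, 12.9% and 13.7%. In a clustering of PDMS with Mock, the gland-like cluster with Krt18 held 17 of 6267 Mock cells (0.271%, exact 95% interval 0.158 to 0.434) and 104 of 5240 PDMS cells (1.98%, 1.62 to 2.40).

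The 6 libraries of each comparison split into 10 pairs of groups, which are too few for a share under 0.05. In X90 against PDMS the real split called 2 genes and the highest other 0, so 1 split gave as many, and for lists the real split called 12 and the highest other 23, with 8 splits giving as many. In PDMS against mock the real split called 2 genes and the highest other 0, with 1 split giving as many, and 16 lists against 23, with 7 giving as many. In X90 against mock every one of the 10 splits called 0 genes with edgeR, where 46 genes had an unadjusted p under 0.05 in the real split and DESeq2 called 0, and the real split called 5 lists against 12, with 9 giving as many. In macrophages the real split called 7938 genes and the highest other 0, with 1 giving as many, and 9 lists against 7, with 1 giving as many. The splits that called 23 lists in skin placed PDMS replicates 1 and 3 together, apart from PDMS replicate 2, which points to a structure of the samples.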
